A study of Homo sapiens with 8 samples.

How the data were processed

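RNA carrying N4-acetylcytidine (ac4C) was captured with an antibody and sequenced beside its input RNA in SiHa cells, a cervical carcinoma line, and in SiHa cells in which NAT10 had been knocked out. The 8 libraries form 4 groups of 2 biological replicates each: input and immunoprecipitated RNA of either population. Per the labels' protocols, the libraries were made with a stranded mRNA kit. The submitters' processing notes name FastQC 0.11.7 and the GRCh38 build (hg38). The aligner, the peak caller, the gene annotation and the way in which replicates were combined are not given in the sources used here.

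The deposited data used here are 2 peak lists, 1 for each population. Each peak has a chromosome, a strand, an Ensembl gene identifier and 1 or more blocks, so a peak can span a splice junction. One list carries the name SiHa and the other the same name with an added K. The second was read as the list of the knockout cells, a reading that no label states in words. In both lists the authors give a p-value for each peak, in a column headed score. In the knockout list the authors also give log10 of the p-value, log10 of the false discovery rate and a fold enrichment, a ratio whose reference is not stated. The p-values and folds are the authors' own and served only to describe, rank or filter peaks within a list. No list gives read counts or a value for a single replicate. The sequencing depth is therefore unknown, and no difference between the lists can be set against the spread between replicates. All intervals below are 95% exact binomial (Clopper-Pearson) intervals, and they cover counting of peaks or genes only. Tests over peaks or genes compare the 2 lists, not the conditions, since neither peaks nor genes are replicates.

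From the SiHa list 1 exactly repeated line and 3 peaks off the assembled chromosomes were left out, and from the knockout list 2 peaks off the chromosomes. Peaks of the lists were called overlapping when blocks on the same strand shared at least 1 base. The chance overlap was estimated from 1000 random placements of each knockout peak within the span of its own gene. Placement in exons and assignment of peaks to genes by exon had been planned, but no exons were at hand, so gene spans and the files' own gene identifiers were used. Those spans include introns, so this estimate is not the chance overlap within exons, which was not measured. A gene with a SiHa peak and no knockout peak is called lost below, a gene with peaks in both lists is called kept, and neither word refers to a measured level of ac4C. Strength was taken as −log10 p in the SiHa list and as fold enrichment in the knockout list. A p-value listed at 0 ranked above all others. Medians of overlapped and other peaks were compared with two-sided permutation tests of 100000 resamples, for which 1e-05 is the smallest p obtainable.

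The files do not pair identifiers with gene names. Names were therefore taken by position from NCBI RefSeq gene spans of the same build. Strand was not used in this step, so a peak antisense to a gene could take its name. An identifier received a name when its peaks touched 1 RefSeq span alone, when at least 90% of their bases lay in it, and when no other identifier had 90% of its bases in that span. Of 9046 identifiers, 6160 (68.1%) received a name. A further 1978 touched several spans, 704 shared a span with another identifier, 121 had too few bases in the span and 83 lay outside every span. As a check of the build, 97.5% of knockout peaks lay inside a span, against 63.4% when all spans were shifted by 1 Mb. The naming rule was made stricter more than once, the last time after list results had been seen. Under the earlier rule, identifiers that touched a further span could not contest a name, and some antisense or neighbouring genes had taken the names of VIM and CD68. The stricter rule was then used for every result, and the earlier one was kept as an alternative. Positional names remain less certain than names from an annotation.

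A total of 27 gene lists with 1064 entries was fixed before the data were examined. For each list the lost share among members with a SiHa peak was compared with the other named genes with a SiHa peak by a two-sided Fisher's exact test. Benjamini-Hochberg adjustment ran over the 23 lists with at least 5 such members. Each share was also placed among 10000 random lists matched on the decile of the strongest SiHa peak. Genes were named in the text by a rule fixed beforehand: NAT10, FOXP1, SLC2A4, KHK and HNRNPUL1 whatever their values, the 10 strongest genes in each of the classes SiHa only, both and knockout only, and up to 4 kept and 4 lost members of each list. Ties went in alphabetical order. Members with a peak in the knockout list alone were added to this rule afterwards, up to 4 for each list by fold. XIST and Y-linked genes were left out.

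The planned split of peaks over transcript regions and the planned sequence analysis need exons and a genome, which were not used here. As a replacement chosen after the data were seen, the midpoint of each peak in a named protein-coding gene was placed in 1 of 10 equal parts of the gene span along the strand of the peak. The overlap step was run on simulated lists made from 12924 peaks, and the recovered share differed from the planted share by at most 1.52 percentage points, since some peaks of a list overlap one another. In 200 simulated lists of 30 genes with 40% lost, in a background of 5000 genes, Fisher's exact test called 96% at an unadjusted p below 0.05, and it called 3.5% of unchanged lists. Most tested lists had fewer members with a SiHa peak, and calls used adjusted p-values, so the 96% does not apply to them. The alternatives concerned the overlap rule, the strand, stricter peak selections, merged peaks, gene assignment, the matching of random lists and the naming rule. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.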

Results

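NAT10 is the acetyltransferase that forms ac4C in RNA. To ask which transcripts carry ac4C in cervical carcinoma cells and which of these peaks depend on NAT10, immunoprecipitated and input RNA was sequenced from SiHa cells and NAT10-knockout SiHa cells, with 2 libraries for each of the 4 groups. The deposited values are 1 peak list for each population. Neither replicate values nor read depths are given, so the comparisons below describe the 2 lists and have no replicate check.

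The NAT10 transcript itself (ENSG00000135372, GRCh38 chromosome 11, 34105629 to 34146908) carried 1 SiHa peak. This peak had 359 bases in blocks between 34142274 and 34146283, and a deposited p of 5e-37. The knockout list held no peak in NAT10. A peak list gives no expression level, so this does not measure loss of the NAT10 transcript.

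The SiHa list held many more peaks than the knockout list. It contained 12924 peaks in 7291 genes, or 1.77 peaks per gene, and the knockout list contained 4557 peaks in 3726 genes, or 1.22 per gene. SiHa cells thus had 2.84 peaks for each knockout peak and 1.96 genes for each knockout gene. The covered length was 3.15 Mb in SiHa and 0.785 Mb in the knockout, a ratio of 4.01. Median peak width was nearly the same, 181 bases in SiHa and 180 in the knockout. The wider peaks differed more, with an upper quartile of 271 bases in SiHa and 181 in the knockout. The mean width was 251 and 176 bases, and the longest peaks reached 2632 and 923 bases. Blocks separated by a gap made up 25.2% of SiHa peaks and 31.3% of knockout peaks. On the mitochondrial chromosome there were 18 SiHa peaks and 4 knockout peaks. In the knockout list, 25% of the peaks (23.8 to 26.3%) had a false discovery rate above 0.05 in the authors' own column. Of all SiHa peak genes, 5320 (73.0%, 71.9 to 74.0%) had no knockout peak and 1971 (27.0%) had one. Conversely, 1755 of the knockout peak genes (47.1%, 45.5 to 48.7%) had no SiHa peak. With the SiHa list reduced to as many of its strongest peaks as the knockout list holds, this order turned: 2189 genes (65.5%) had a SiHa peak alone and 2573 (69.1%) a knockout peak alone. The reduced list covered 3342 genes and the knockout list 3726. Since the shared genes are the same in both, the order of these counts only restates the totals.

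Among genes with a SiHa peak alone, 88 named genes had a p listed at 0, so the first 10 by the fixed rule stand in alphabetical order and not in order of strength. They were ACTB and ACTN1, which encode cytoskeletal actin and an actin crosslinker, AGPAT3, AKAP12, ANKRD40, the co-chaperones BAG3 and BAG5, BAMBI, C12orf75 and CALR, which encodes the endoplasmic reticulum chaperone calreticulin. ACTB had 2 SiHa peaks, the strongest of 419 bases at chromosome 7, 5527450 to 5527868. AKAP12 had 5 peaks, the strongest with 1079 bases between 151352871 and 151355923 on chromosome 6.

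Among named genes with peaks in both lists, 91 had a SiHa p listed at 0. Those that came first in alphabetical order included ADAR, AHNAK, AMBRA1, AMOTL1, ANKLE2, ANP32B, ANTXR2, ARF6 and ARHGAP29. A peak in both lists was not always a peak at the same place. Of the 17 SiHa peaks of AHNAK, 5 were overlapped by a knockout peak. ARF6, a small GTPase of membrane traffic, had overlapping peaks on chromosome 14, of 690 bases in SiHa and 390 bases in the knockout with a fold of 18.1. None of the SiHa peaks of ANKLE2, ANP32B and ARHGAP29 was overlapped.

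Among named protein-coding or long noncoding genes with a knockout peak alone, the highest folds were 603 in TXNDC11-AS1 and 567 in FAM157D. Next came 377 in GPC2, a cell-surface proteoglycan, and 313 in IKZF3, a lymphoid transcription factor. DHRS2 followed with 310, ATG4D, an autophagy protease, with 300, LINC00504 with 279, RXRA, a nuclear receptor, with 269, and P2RY8 and WFDC2 with 228 each. The peaks behind these folds lay on the repeated series described below, except that of ATG4D. Whether folds on and off that series share a scale is not known, so the order is only that of the deposited values.

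Of the other genes fixed beforehand, KHK, which encodes ketohexokinase, had 1 SiHa peak, with a deposited p of 0.0012, and no knockout peak. In the span of FOXP1, which encodes a forkhead transcription factor, 2 identifiers each had a SiHa peak and neither had a knockout peak, so the name could not be assigned to 1 of them by the naming rule. No peak lay in SLC2A4, which encodes the insulin-responsive glucose transporter. HNRNPUL1 had a SiHa peak at chromosome 19, 41264696 to 41264983, with a deposited p of 6.3e-42, and a knockout peak elsewhere in the gene, at 41306523 to 41306672, with a fold of 3.42 and a deposited p of 0.0051. Another identifier, with most of its peak bases elsewhere, also had a SiHa peak that reached into this span.

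At the level of single peaks the lists shared little. A knockout peak overlapped 874 of the 12924 SiHa peaks, 6.76% (6.34 to 7.21%), and a SiHa peak overlapped 876 of the 4557 knockout peaks, 19.2% (18.1 to 20.4%). Within genes that had peaks in both lists the shares were 20.5% of SiHa peaks and 34.1% of knockout peaks. Of 3165 knockout peaks in named genes, 19% were overlapped, against a mean of 2.92% (range 1.99 to 3.70%) over random placements in the same gene spans. The random placements could fall in introns, and the overlap that placement within exons would give was not measured. This comparison therefore cannot show that the overlap exceeded chance. Exactly the same blocks were found in both lists for 41 peaks.

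Stronger SiHa peaks were overlapped more often. The median −log10 p was 16.9 in overlapped SiHa peaks and 5.60 in the others, a difference of 11.3 (permutation p = 1e-05, the smallest obtainable). The difference was 2.91 when overlap was reciprocal over 50% of both peaks, and 21.2 against the knockout peaks off the repeated series described below. Overlapped SiHa peaks were also wider, with a median of 270 against 181 bases (permutation p = 1e-05, the smallest obtainable). In the knockout list the median −log10 p was 8.26 in overlapped peaks and 4.94 in the others (permutation p = 1e-05, the smallest obtainable). The median fold went the other way, 11.8 in overlapped peaks and 12.8 in the others (permutation p = 0.0207). This comparison mixes peaks on and off the repeated series described below, whose median folds were 20.5 and 7.69. The series held 28.7% of the overlapped knockout peaks and 50.9% of the others. Genes in the lowest decile of SiHa peak strength had a knockout peak in 14.5% of cases (12 to 17.3%), and those in the highest decile in 43.1% (39.4 to 46.8%). Of the 281 genes with a SiHa p listed at 0, 149 had no knockout peak.

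**Figure D1:**
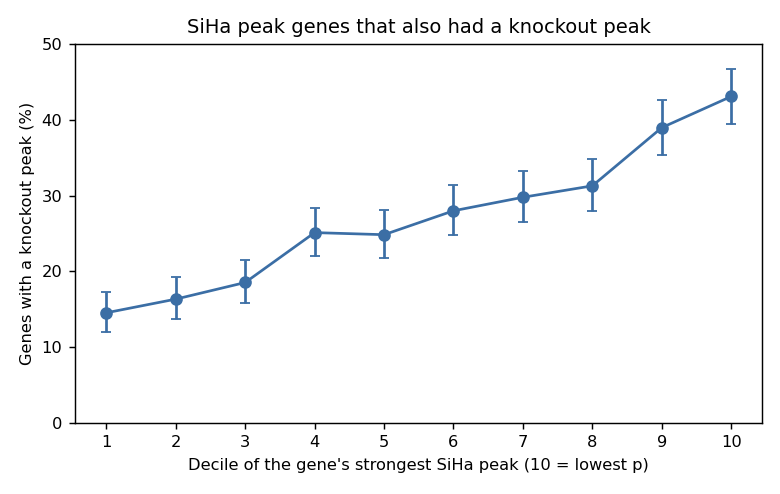
Share of SiHa peak genes that also had a knockout peak (y axis, percent) by decile of the gene's strongest SiHa peak (x axis, 10 with the lowest p). Points are shares of 729 or 730 genes with 95% exact binomial intervals, and they run from 14.5% in the lowest decile to 43.1% in the highest.

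Among 4945 named genes with a SiHa peak, 3585 (72.5%) were lost, and of 23 tested lists, 1 differed from this background after adjustment. The lists share genes, so their tests are not independent. SiHa peaks were found in 26 of 35 RNA modification enzymes, 30 of 55 chromatin regulators, 22 of 39 Notch and Wnt genes and 31 of 79 cytosolic ribosomal proteins. They were found in 3 of 45 oxidative phosphorylation subunits and 2 of 50 replication-dependent histones. Members whose peaks received no unique name count as having none here, and expression was not known.

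Chromatin regulators were lost less often than other genes: 11 of 30 (36.7%, 19.9 to 56.1%) had no knockout peak, against a mean of 66.7% in strength-matched random lists, a percentile of 0.04 (Fisher's exact adjusted p = 0.000964). The histone demethylases KDM5A and KDM5B, the SWI/SNF subunit ARID1A and the nucleosome remodelling factor BPTF had peaks in both lists. The acetyltransferase KAT6A, with 8 SiHa peaks, the methyltransferases NSD1 and NSD3 and the DNA methyltransferase DNMT3A had none in the knockout. SETD1A and TET3 were among 7 members with a knockout peak alone. Over all genes with peaks in both lists, 20.5% of SiHa peaks were overlapped, so peaks at different places were common. The peaks of kept chromatin regulators also lay largely at different places, since 5 of the 19 kept genes had a SiHa peak that a knockout peak overlapped. When a gene without such an overlap counted as lost, the share was 83.3% against a background of 89.1% (exact adjusted p = 0.709). The difference from the background also missed the threshold when knockout peaks of the repeated series described below were left out (66.7% lost, background 82.0%, exact adjusted p = 0.196) and when only peaks with −log10 p above 8 were used (75% lost, background 84.4%, exact adjusted p = 0.477).

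A further 3 lists had an unadjusted Fisher's exact p below 0.05 and missed the adjusted threshold. Pre-mRNA splicing factors were lost in 8 of 17 genes (percentile 1.82 of the matched random lists, exact adjusted p = 0.209). The percentile was 0.345 off the repeated series. When loss was counted by overlap, 15 of 17 were lost (88.2%, background 89.1%, percentile 46.8), so the kept members had peaks largely at different places. SNRPD2 and PRPF19 were lost, PRPF38B and SON were kept, and 11 members including TRA2B and DDX5 had a knockout peak alone. In cell adhesion, cytoskeleton and epithelial-mesenchymal transition, 11 of 23 genes were lost (percentile 8.46, exact adjusted p = 0.187). ACTB, ACTN1, the hyaluronan receptor CD44 and the myosin MYH9 were lost, and AHNAK, FLNA, ITGA3 and DST were kept, with 26 SiHa peaks in DST. This list passed the threshold in the knockout peaks off the repeated series (exact adjusted p = 0.00464) and when loss was counted by overlap (exact adjusted p = 0.0493). Among strength-matched random lists its share stood at percentile 0.865 in the first of these settings and at 6.49 in the other, which lies inside the central 95%. Collagens and extracellular matrix genes were lost in 3 of 8 cases (percentile 1.5, exact adjusted p = 0.233). When loss was counted by overlap, 7 of 8 were lost (percentile 36.3), and off the repeated series the percentile was 7.2. Their kept members included TNC, with 5 SiHa peaks, and NID1, with a knockout fold of 300.

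Notch and Wnt signalling had the highest lost share among the tested lists, 19 of 22 genes (86.4%, 65.1 to 97.1%). The Notch ligand JAG1, the Wnt receptors FZD7 and LRP6 and the ligand WNT5B were lost, while NOTCH1, NOTCH2 and AXIN2 were kept. The share stood at percentile 97.3 of the random lists, and the exact adjusted p was 0.527. The percentile was 97.7 with gene span matched as well and 98.5 with covered bases matched instead of span. It was 98.4 off the repeated series and 98.3 with the protein-coding naming. With the SiHa list reduced to its strongest peaks it fell to 93.5. When only peaks with −log10 p above 8 were used, 88.2% were lost (background 84.4%, percentile 68.0). When loss was counted by overlap, 90.9% were lost (background 89.1%, percentile 76.1). In growth factor signalling through PI3K, mTOR and MAPK, 17 of 27 genes were lost, among them EGFR with 6 SiHa peaks and MET with 4, and IGF1R, IRS2 and TSC1 were kept (exact adjusted p = 0.540).

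The translation machinery did not differ from the background past the adjusted threshold. Cytosolic ribosomal proteins were lost in 18 of 31 genes, including RPS14 and RPL14, with RPS24 and RPL37 kept (exact adjusted p = 0.340). Their share stood at percentile 8.26 of random lists matched on strength and at 1.76 of those matched on strength and gene span. Off the repeated series the percentile was 2.08. When loss was counted by overlap, 29 of 31 ribosomal protein genes were lost (percentile 85.0). Initiation and elongation factors were lost in 10 of 19 genes, including EIF3A and EEF1A1, with EEF2 and PABPC1 kept (exact adjusted p = 0.281). Nucleolar ribosome biogenesis genes were lost in 14 of 25, including NOP2 and DKC1, with NCL and NPM1 kept (exact adjusted p = 0.281). This list stood at percentile 8.43 of the random lists, and at 1.21 with the protein-coding naming. The heterogeneous nuclear ribonucleoproteins were lost in 5 of 10 genes, and HNRNPDL had a knockout peak alone with a fold of 167 (exact adjusted p = 0.385). RNA modification enzymes were lost in 17 of 26 genes, including the m6A reader YTHDF2 and the pseudouridine synthases PUS1 and PUS7, with ADAR and RBM15 kept (exact adjusted p = 0.637).

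In metabolism, glycolysis and lactate genes were lost in 6 of 10 cases, among them PFKFB3 and the lactate transporter SLC16A1, while the glucose transporters SLC2A1 and SLC2A3 were kept (exact adjusted p = 0.732). Fatty acid and cholesterol synthesis genes were lost in 11 of 14 cases, including ACLY. SQLE was kept, and FASN had 4 knockout peaks and none in SiHa (exact adjusted p = 0.924). Ferroptosis and redox genes were lost in 5 of 7 cases, with KEAP1 lost and NFE2L2 kept (exact adjusted p = 1). Mitochondrially encoded genes were lost in 6 of 9 cases, including CYTB and ND5, with COX1 and ND1 kept (exact adjusted p = 0.924).

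In growth and stress, cell cycle genes were lost in 8 of 13 cases, with CDKN1A, CDKN1B and RB1 lost, CCND1 and MKI67 kept, and PLK1 among 9 genes with a knockout peak alone (exact adjusted p = 0.637). DNA replication and repair genes were lost in 12 of 16 cases, including FEN1 and MCM3 (exact adjusted p = 1). Chaperones were lost in 14 of 20 cases, with CALR and HSPA5 lost and HSP90AA1 and HSP90AB1 kept (exact adjusted p = 0.924). Genes of the p53 pathway and apoptosis were lost in 9 of 15 cases, with GADD45A lost and MCL1 kept (exact adjusted p = 0.540). Proteasome and ubiquitin genes were lost in 8 of 15 cases, with PSMD4 lost and PSMC3 kept (exact adjusted p = 0.385). Interferon and antigen presentation genes were lost in 8 of 12 cases, with IFNAR1 lost and HLA-E kept (exact adjusted p = 0.924). Squamous keratinocyte markers were lost in 4 of 6 cases, with KRT5 and KRT13 lost and KRT19 kept (exact adjusted p = 0.924). Genes named in earlier work on NAT10 and ac4C were lost in 10 of 14 cases, including SOX4, BCL9L and NAT10, and kept in HSP90AA1, HNRNPUL1, SEPTIN9 and AKT1 (exact adjusted p = 1). NAT10 is itself a member of this list and of the lists of ribosome biogenesis and RNA modification.

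Another 4 lists had too few members with a SiHa peak for a test. Oxidative phosphorylation subunits were lost in 3 of 3 genes, replication-dependent histones in 1 of 2, and abundant nuclear noncoding RNAs in 2 of 3. In the list of markers of cells absent from a cell line, 0 of 4 genes were lost: the globin genes HBA1, HBA2 and HBB and the liver gene ALB were kept, and PECAM1 and PTPRC had a knockout peak alone. Under the earlier naming rule this last list had 5 members, again none lost, and passed the threshold (exact adjusted p = 0.0182). The added member was CD68, a name that another gene had taken under that rule, so this call rests on a wrong name. With the protein-coding naming 1 of 5 was lost (exact adjusted p = 0.130), and off the repeated series 3 of 4 were lost.

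**Figure D2:**
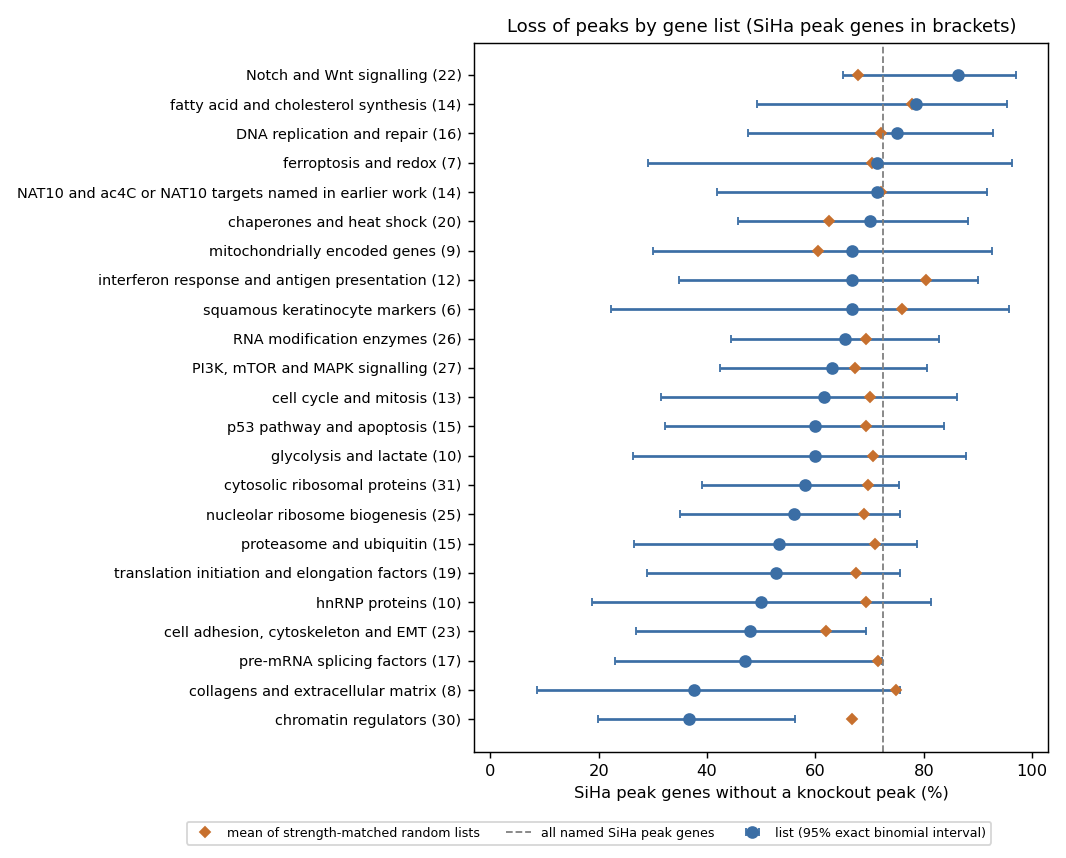
Share of SiHa peak genes without a knockout peak (x axis, percent) for the 23 tested gene lists, with the number of SiHa peak genes in brackets. Circles are list shares with 95% exact binomial intervals, diamonds are means of strength-matched random lists and the dashed line marks 72.5% of all named genes; chromatin regulators lie lowest, at 36.7%.

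In both lists the last 10% of the gene span held more peaks than any other of the 10 parts, and more so in SiHa. In named protein-coding genes, 41.8% of 8389 SiHa peaks and 32.9% of 3008 knockout peaks had their midpoint in the last 10% of the gene span (difference 8.89 percentage points, Fisher's exact adjusted p = 2.29e-17 over 12 position tests). In the first 10% of the span the shares were 7.08% and 7.61% (exact adjusted p = 0.414). A span includes introns and all transcripts of a gene, so these parts do not stand for coding sequence or untranslated regions. Names were given without regard to strand, so a peak antisense to its named gene was counted from the wrong end. The share that random positions in exons would give was not measured. The lists hold partly different genes and the test was not restricted to shared ones. A difference between genes therefore cannot be told from a difference in position. Several peaks of one gene counted separately, so the p may be too small.

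**Figure D3:**
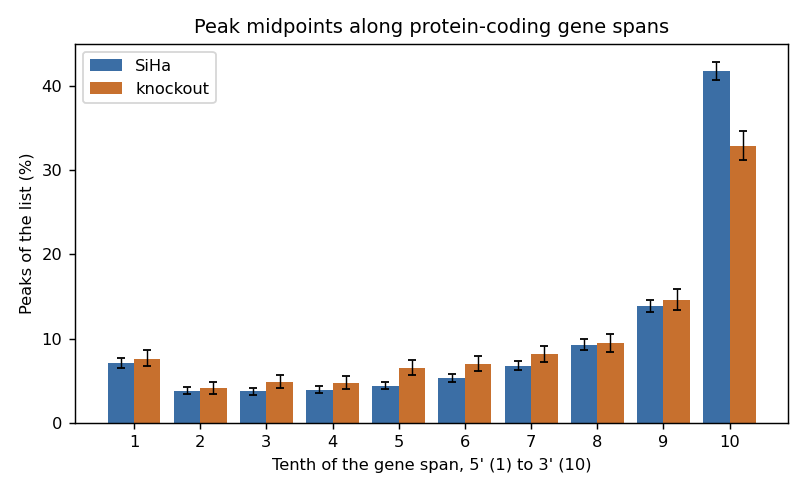
Share of peaks (y axis, percent of the list) by the part of the gene span, out of 10 equal parts, in which the midpoint lies (x axis, 1 at the 5′ end and 10 at the 3′ end) in named protein-coding genes, with 95% exact binomial intervals. The last part holds 41.8% of SiHa and 32.9% of knockout peaks.

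Many knockout peaks fell on a single line of fold against p. In 2124 of the 4557 knockout peaks (46.6%, 45.2 to 48.1%), the fold was more than 3.5 times −log10 p. Of these, all 1965 with a fold under 100 had a fold within 1% of a whole multiple of 2.56, against 27.6% of the peaks off this series. The lowest fold on the series was 7.69, or 3 such steps. The folds given above for NID1 and HNRNPDL also lay on it. The series held 28.7% of the overlapped knockout peaks and 50.9% of the others (Fisher's exact p = 2.89e-33). A SiHa peak overlapped 11.8% of the knockout peaks on the series and 25.7% (24.0 to 27.5%) of those off it. The 10 commonest p-values covered 33.8% of the knockout peaks, of which 90.8% lay on the series, and 35.1% of the SiHa peaks. The SiHa list has no folds in which to look for such a series, so the results off the series filter the knockout list alone.

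**Figure D4:**
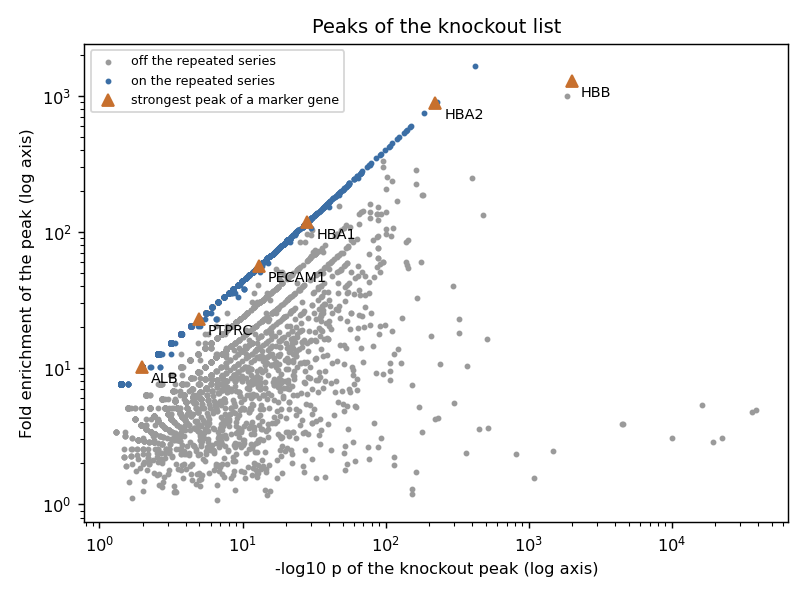
Fold enrichment (y axis, log scale) against −log10 p (x axis, log scale) for the peaks of the knockout list, each point 1 peak. Peaks on the repeated series form the upper edge, and triangles mark the strongest peak of each marker gene, with HBB at a fold of 1290.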

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

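No paired analysis was possible because each population has a single list with no values for its replicates, and for the same reason no replicate was left out. The selection above −log10 p of 8, the restriction to knockout peaks off the repeated series (the SiHa list unfiltered), the protein-coding naming of list members, the earlier naming rule and every position result were chosen after seeing the data. Not run were the second strength column, which the SiHa list lacks, transcript regions with their summit or every-base version, and the sequence analysis with its shuffled control. Depth is unknown, so fewer knockout peaks cannot be separated from fewer reads.

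With the same stricter p in both lists there were 4.28 SiHa peaks per knockout peak, and 5.31 off the repeated series. The overlapped share of SiHa peaks was 3.15% with a reciprocal overlap of 50%, 5.50% with 50% of the shorter peak, 4.32% in the stronger 50% of each list, 11.3% with the SiHa list reduced to the knockout list's length, 5.76% above −log10 p of 8 and 4.87% off the series. For knockout peaks the first 4 of these settings gave 8.98%, 15.9%, 12% and 11.7%, and the last gave 25.7%. Genes with a SiHa peak alone numbered 3375 among named protein-coding genes, 2189 with the reduced SiHa list and 3349 above −log10 p of 8. Genes in both lists numbered 1153 with the reduced list, 602 above 8 and 1278 off the series. Genes with a knockout peak alone numbered 1091 among protein-coding genes, 867 above 8 and 828 off the series. With the reduced list, which covered fewer genes than the knockout list, they rose to 2573 and outnumbered the genes with a SiHa peak alone. Lists past the adjusted threshold numbered 0 above 8, where 2 had an unadjusted Fisher's exact p below 0.05, and 2 under the earlier naming rule. Among the latter was the marker list, which then held the wrongly named CD68. The causes were not tested. Of single list results, 148 stayed on their side of the threshold, 3 (chromatin regulators) ended and 2 (cell adhesion) passed it. The 148 include all results of the setting that changed only the matching of random lists. That matching does not enter Fisher's exact test, so those results could not move. The strength difference was 2.91 with the reciprocal overlap and 21.2 off the series, and it and the excess of SiHa peaks in the last 10% of the gene span kept direction and call in these and the other settings run.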

Other observations

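The tests of the first 2 explanations for the small overlap and both tests on the marker genes were chosen after their results had been seen. Those on chromatin regulators were written before their own results but after the list had stood out.

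Transcripts best known from blood, vessel and liver cells carried peaks. HBB, the adult beta-globin gene, had 2 peaks in each list, and its knockout fold of 1290 ranked 2 among all knockout peaks. HBA2 reached 887, at rank 5, and HBA1 reached 118. These alpha-globin copies are nearly identical, and their peaks cannot be told apart with certainty. ALB, which encodes serum albumin, had a SiHa peak with a deposited p of 1e-201 and a knockout peak with a fold of 10.3 at a different place. The endothelial gene PECAM1 (56.4) and the leukocyte gene PTPRC (23.1) had a knockout peak alone. Of the 21 markers fixed beforehand, 6 were named and had a peak.

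The median highest fold of these 6 markers was 87.2, against 14.95 in random lists of knockout peak genes, a percentile of 99.89. Under the earlier naming rule, with 7 markers, the median was 118, but the added marker was CD68, a name that another gene had taken. RNA of other cells in the immunoprecipitated libraries is a candidate explanation, but the test was made from the values that drew attention and cannot establish it. Expression by the SiHa cells stays open as well: 4 markers had a peak in both lists, and input levels, which would decide, were not used here. In 5 of the 6 markers every knockout peak lay on the repeated series, HBB being the exception, and no biological explanation was tested.

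The 2 lists shared few peaks, 19.2% of the knockout peaks. If the knockout list were a shallower sample of the SiHa sites, its peaks of lowest p should mostly recur (over 50%, a bar set afterwards). Of those with −log10 p above 8, 27.6% (25.4 to 29.8%) were overlapped, below this bar. Without replicate lists, how often such peaks recur between 2 lists of the same cells is not known. The share therefore cannot decide on this explanation. Peaks that rest on few reads without input reads stay open: 25.7% of the peaks off the repeated series were overlapped, but the lists hold no read counts, so which peaks rest on few reads is not known. The spread between libraries of one population stays open, since there was 1 list per population. Loss of NAT10 and this spread cannot be told apart.

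Chromatin regulators kept peaks in more genes than the background did. Chromatin regulators have long spans, with a median of 110 kb against 34.2 kb. Against random lists matched on span and strength the lost share still stood at percentile 0.155. This argues against gene span as the whole cause. Spans include introns, so the length of the spliced transcripts was not matched, and it stays open as a cause. Weak knockout peaks without input reads stay open: 9 of the 19 kept members (47.4%, 24.4 to 71.1%) had all their knockout peaks on the repeated series. This range includes 50% and no read counts show which peaks are weak, and leaving the series out raised the lost share to 66.7%, against a background of 82.0%, and ended the call. A property of these transcripts is a hypothesis that these lists do not establish.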
